A study of Mus musculus with 68 samples.

How the data were processed

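Total RNA of mouse mammary tumours was extracted with Trizol and RNeasy columns, labelled with biotin by the one-cycle kit and hybridised to Affymetrix arrays, per the labels' protocols. The table holds 68 arrays and 45101 probe sets, 64 of them control probe sets, with 0 missing values. The deposited values are RMA values, per the submitters' processing notes. RMA corrects background, normalises between arrays and summarises probes into probe sets. No version, settings or log base are given in the sources used here. Per the labels, no scale is named, and the deposited values are read here as log2 from their range, 1.68 to 14.57, with a median of 5.42. Whether all arrays were normalised together is not given in the sources used here. Scanner images and raw probe intensities were not used here, so the normalisation was not repeated. The number of arrays limits the precision. Signal over background was not used here.

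Gene names came from the platform annotation given with the data. It lists 35890 probe sets, 34958 with 1 gene, 932 with several genes and 9211 of the probe sets not listed. Of those with 1 gene, 34754 were found in the reference gene table (GRCm38.p6). The build of the array is not named, so that table served only for names, chromosomes and for which genes lie within 10 Mb of each other. No gene was named from a probe set with several genes. Each gene was represented by its probe set with the highest mean. A gene was tested if the 95th percentile of its values lay above the median of all values (5.42), which left 12900 genes.

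The labels form 1 group. Arrays sharing an animal number were averaged, which gives n = 66 animals. The test of the suffix R used all 68 arrays as separate samples, so 2 animal numbers enter it with 2 arrays each. Animal numbers were divided at 4000, where they leave a wide gap.

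Technical batches were searched for in the values. A split of the arrays was taken as an array set if at least 20 probe sets on at least 10 chromosomes shared it exactly, with Ashman's D (the distance of the 2 means over the root mean square of their SDs) over 4.5 and at least 15% of arrays on the smaller side. The search found array sets 2, 3 and 4 in turn and stopped, and array set 1 is the remainder. Array sets are not the study's groups. The 18S ribosomal RNA control probe sets were singled out after their values were seen. The Gapdh and Actb 3' minus 5' differences served as measures of RNA quality.

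Before the data were examined, 29 gene lists with 455 genes, the tests, the alternatives and the rule for named genes were fixed. The lists cover cell types, tissue of other kinds that a tumour piece can hold, cell processes, loci known to differ between mouse strains, and genes reported to modify metastasis. 28 lists had at least 5 measured members. The erythroid list had 1, Alas2, with a mean of 5.97 and an SD of 0.58, and was not tested. List variability was tested with Fisher's exact test, one-sided, among the 5% of genes with the largest SD. List coherence is the median pairwise Pearson correlation of a list's genes, tested one-sided against 10000 random lists matched on mean expression in 20 bins. A list score is the mean z-score of its measured genes. Correlations within array sets 1 to 4 used the genes and probe sets chosen over all animals, while array set 1 as an alternative had both chosen anew, so that the values of r for array set 1 differ slightly between both. Pairs of scores were tested by permutation with 100000 draws, two-sided. Genes were fitted on each of 4 standardised scores with limma (lmFit and eBayes), leaving out the list's own genes, and on the suffix and number range in the same way. All adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05.

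For two-cluster genes, the values of the 66 animals were split by least squares with at least 20% of animals on the smaller side. The p of D came from 1e+06 simulated uniform samples, the flattest distribution with 1 peak. The side sizes were tested against 1:1 with an exact binomial test, two-sided. Agreement of 2 genes is the percent of animals on the same side, or on opposite sides where that is larger. Agreement of neighbours within 10 Mb was tested by 10000 permutations of the genes' positions, one-sided.

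The rule for named genes takes the 30 genes with the largest SD, the 25 two-cluster genes with the largest D and all measured members of the strain loci list, and for each score the 10 most positive and 10 most negative correlations among genes of no list past the threshold. It also takes up to 4 members per list by SD and 4 by correlation with the rest of the list, all measured metastasis modifiers, and the 10 largest changes each way for the suffix and the number range. Genes outside this rule are said to be chosen after their values were seen.

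The alternatives were the 68 arrays as separate samples, the numbers with 2 arrays left out, another choice of probe set, no filter or a stricter filter, probe sets ending in _x_at or _s_at left out, either number range alone or as a covariate, residuals after the 3' to 5' difference, other thresholds and nulls for two-cluster genes, and other scores and correlations. After the data were seen, leaving out array set 2, array set 1 alone, centring within array sets, array set as a covariate, and array set 1 with a null of normal samples were added. Because of these sets, counts of calls and correlations are given for array set 1 beside all animals, except for the suffix R, since array set 1 holds 0 arrays with R.

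The tests were tried on simulated data, which held no array sets. Simulated two-cluster genes with means 5 SD apart were called in 72% of cases with 66 samples and in 20% with 39, and at 6 SD in 100% and 80%. The null of normal samples with 39 samples called 90% at 5 SD, but also 10.7% of flat genes without clusters and 0.0732% of normal ones. For a score, limma called 40% of genes with a simulated correlation of 0.4 and 100% of those with 0.7 with 66 samples, and 14% and 92% with 39. The pair test called 12.5%, 10% and 10% of 40 simulated pairs without correlation at an unadjusted p under 0.05 with 66, 39 and 8 samples, and 4.4%, 5.1% and 5.0% of 1000 such pairs simulated afterwards because of these values. A correlation of 0.8 was called in 60% of 40 pairs with 8 samples, and one of 0.4 in 12.5%. A simulated log2 difference of 0.5 was called in 63% of genes for the suffix and 85% for the number range. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.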

Results

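Gene expression was measured in spontaneous mammary tumours of mice that carried the MMTV-PyMT transgene, which drives the polyoma virus middle T oncogene in mammary epithelium. The animals came from a backcross of (NZB x PyMT) hybrids to FVB. If the PyMT line is on FVB, as the widely used line is, each autosomal locus of an animal is either FVB on both chromosomes or NZB on 1 and FVB on the other. The 68 arrays form 1 group of 66 animal numbers, from 2421 to 5000. The numbers lie in a lower range of 48 animals, up to 3891, and an upper range of 18 animals, from 4946. The titles of 10 arrays end in R, a mark whose meaning is not given in the sources used here, and the numbers 3296 and 3351 occur with and without it. With 1 group, the questions open to the data are which genes and cell types varied between tumours, which varied together, and which genes fell into separate levels as the 2 genotypes of a backcross would give.

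The arrays fell into sets that the labels do not name. In 12 arrays, array set 2, the mean of the 18S ribosomal RNA probe sets was 9.63 ± 0.37 (log2, SD, n = 12), against 5.90 ± 0.40 in the other 56, and the lowest of the 12 (8.97) lay above the highest of the 56 (6.84). The spread of values within an array was narrower there, with an SD of 2.04 ± 0.03 against 2.33 ± 0.03. The split of these 12 arrays was shared exactly by 2434 probe sets on 22 chromosomes, of which 529 were higher and 1905 lower in the 12. Array set 3 held 9 arrays, 8 of them with R, set apart by 44 probe sets on 14 chromosomes. Array set 4 held 8 arrays, all of the upper number range, set apart by 121 probe sets on 18 chromosomes. The other 39 arrays are array set 1, with 35 lower and 4 upper numbers and 0 with R. The first principal component held 34.7% of the variance, 97.7% of it between array sets, and the median SD of a gene was 0.33 over all animals and 0.19 within array set 1. Counts of calls and correlations below are therefore given for array set 1 as well, except for the suffix R, which that set does not hold.

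**Figure D1:**
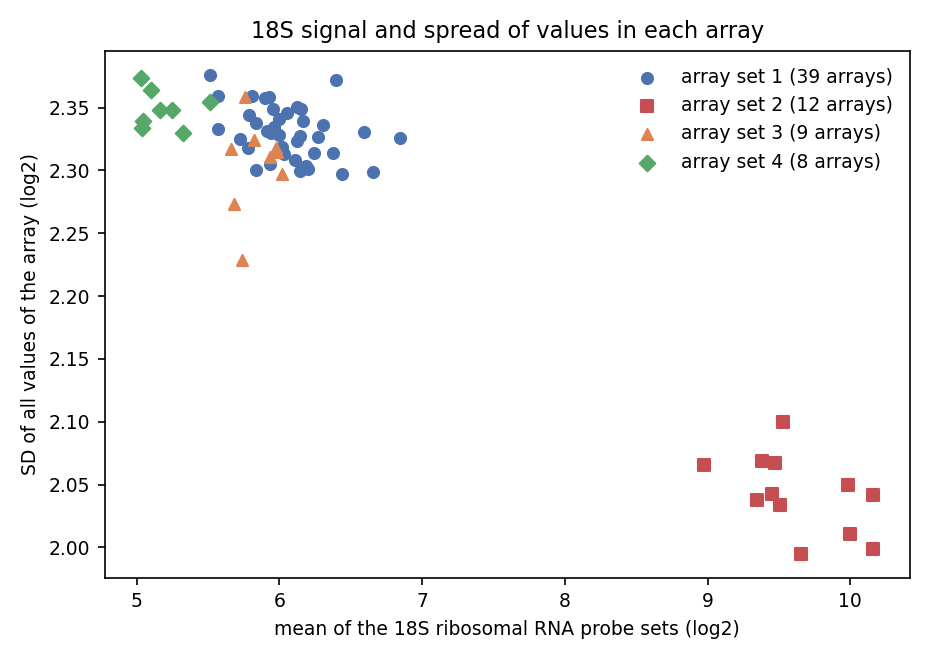
Each point is 1 array, with the mean of its 18S ribosomal RNA probe sets (log2) on the x axis and the SD of all its values (log2) on the y axis, marked by array set. The 12 arrays of array set 2 lie at 8.97 or more on the x axis, and the other 56 at 6.84 or less.

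The 2 animal numbers with 2 arrays each had 1 array in array set 1 and the R array in array set 2. For number 3296, the Pearson correlation of the 2 arrays across genes was 0.930, rank 393 of the 580 pairs of an R and a non-R array. For number 3351 it was 0.929, rank 400. Genes are not independent replicates, so only the ranks are compared. After centring within array sets, the 2 arrays of 3296 were the most alike of the 580 pairs (rank 1, r = 0.990), and those of 3351 ranked 206 (r = 0.972). At the 9 two-cluster genes described further on, the arrays of 3296 lay on the same side for 7 genes and those of 3351 for 5, while 670 pairs of arrays of other numbers, 1 of each pair in array set 2, had a median of 4. Of these, 48 were at least as alike as the arrays of 3296 and 307 as those of 3351. Rab1b counted against both numbers, at 9.42 and 8.22 in the arrays of 3296 and 9.44 and 8.26 in those of 3351. Its level largely followed the array sets, so that mismatch does not bear on identity. H2-Eb1 and D17H6S56E-5 split 96.97% of animals alike, so the 9 genes are not independent markers. BC018473 stood at 3.85 in array 3351 and 10.10 in array 3351R, Mir1931 at 6.07 and 3.40, and the B cell marker Ms4a1 at 3.60 and 5.80. Whether the 2 arrays numbered 3351 hold 1 animal is therefore open, and their mean for BC018473 lies between the 2 levels of that gene.

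Skeletal muscle genes were the largest listed group among the 30 genes with the largest SD between tumours. Myh4, a fast myosin heavy chain, had a mean of 8.32 and an SD of 2.70 (log2, n = 66) and ranged from 3.02 to 12.54. Tnnc2 (SD 2.54), Myh1 (2.39), the skeletal alpha-actin Acta1 (2.25) and Tnnt3 (2.18) followed, as did Ttn (2.30), Neb (2.09), Myom2 (1.95), Myot (1.86), Mybpc2 (1.82) and Smpx (1.76), muscle genes that are in no fixed list. Prr9 (2.65), the hair follicle protein Tchh (2.62), Rptn (2.11), Crct1 (1.81), the follicle keratin Krt25 (1.76), Krtap8-1 (1.73) and Sprr1a (1.74) are genes of hair and cornified skin. Glycam1, a mucin secreted into milk, ranged from 3.03 to 12.91 with an SD of 2.38. The largest SD of the genes tested was that of BC018473 (4.02), and St6galnac1, a sialyltransferase (1.93), Wif1, a secreted Wnt inhibitor (1.91), and Pip, a secretory gland protein (1.75), were also among the 30 most variable. Of these 30, 12 were in the skeletal muscle list, 1 each in the milk and skin lists and 16 in no list, and 27 were also among the 30 most variable in array set 1.

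By fixed lists, the most variable genes included markers of muscle, fat, skin and salivary gland, and genes of secretion and of interferon response. Mitosis and DNA replication genes were not among them. Whether such markers came from other tissue in the piece or from tumour cells was not tested. All 11 measured adipocyte genes, such as Adipoq (SD 1.71) and Car3 (1.34), were in the top 5% by SD, as were all 13 of squamous epithelium and skin, such as Krt6b (1.65) and Calm4 (1.56). The counts were 15 of 16 for skeletal muscle, 13 of 17 for milk protein and secretion (Csn1s2a 1.65, Csn2 1.33), 9 of 17 for interferon response (Oasl2 1.06, Ifit3 1.02), 5 of 7 for salivary gland (Prol1 1.60, Amy1 1.49), 6 of 18 for hypoxia and glycolysis (Adm 0.92, Car9 0.90) and 5 of 9 for B and plasma cells (Jchain 1.45). They were 4 of 11 for basal cells (Krt17 1.20, Krt14 0.85), 3 of 7 for MHC class II (H2-Eb1 1.29), 3 of 8 for neutrophils (S100a9 1.37) and 4 of 21 for fibroblasts and matrix (Col1a1 0.83). These 12 of the 28 lists tested passed Fisher's exact test, one-sided, with adjusted p from 1.12e-17 for skeletal muscle to 0.0438 for fibroblasts. The count was 2 of 13 for luminal cells, 2 of 15 for immediate early genes, 2 of 7 for strain loci, 1 of 12 for T and NK cells, 1 of 12 for fatty acid synthesis, 1 of 10 for mesenchymal transition and 1 of 7 for peripheral nerve. It was 0 for mitosis, DNA replication, cholesterol synthesis, cytosolic ribosome, endothelium, macrophages, oxidative phosphorylation, the unfolded protein response and metastasis modifiers. Within array set 1, 11 lists passed, 10 of them the same. The fibroblast (adjusted p = 0.466) and MHC class II lists (0.0954) did not, and T and NK cells did, with 4 of 12 genes (0.00621).

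Most lists rose and fell as units between tumours. Members of the skeletal muscle list had a median pairwise Pearson correlation of 0.953, adipocyte genes 0.878 and interferon genes 0.841, with Usp18, an interferon-induced protease, following the rest of its list most closely (r = 0.973). Mitosis genes stood at 0.820, led by the checkpoint kinase Bub1 and Cdk1, DNA replication at 0.770, fibroblast and matrix genes at 0.742 and macrophage genes at 0.706, led by Tyrobp. Squamous and skin genes had 0.656, hypoxia 0.597, B and plasma cells 0.576, MHC class II 0.532, endothelium 0.487, T and NK cells 0.388, mesenchymal transition 0.285 and neutrophils 0.256. With cytosolic ribosome (0.886), oxidative phosphorylation (0.861) and cholesterol synthesis (0.738), these 18 of 28 lists passed the test against matched random lists, with adjusted p from 0.00028, the smallest the 10000 draws gave after adjustment, to 0.0208. The milk list (0.578, adjusted p = 0.137), the basal list (0.374, 0.0619), the luminal list (0.405, 0.592), fatty acid synthesis (0.501, 0.592) and immediate early genes (0.291, 0.603) did not pass over all animals. They passed in array set 1 alone, which gave 23 lists, with lower correlations of 0.53, 0.14, 0.13, 0.40 and 0.17 in that order. The median of their matched random lists was 0.116 to 0.489 over all animals and -0.00258 to 0.0169 in array set 1. Salivary gland (0.0354), peripheral nerve (0.0960), strain loci (0.0944), the unfolded protein response (0.342) and metastasis modifiers (0.333) passed in neither. The median correlation of ribosome genes was 0.383 within array set 1, that of oxidative phosphorylation 0.546 and that of luminal genes 0.131.

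**Figure D2:**
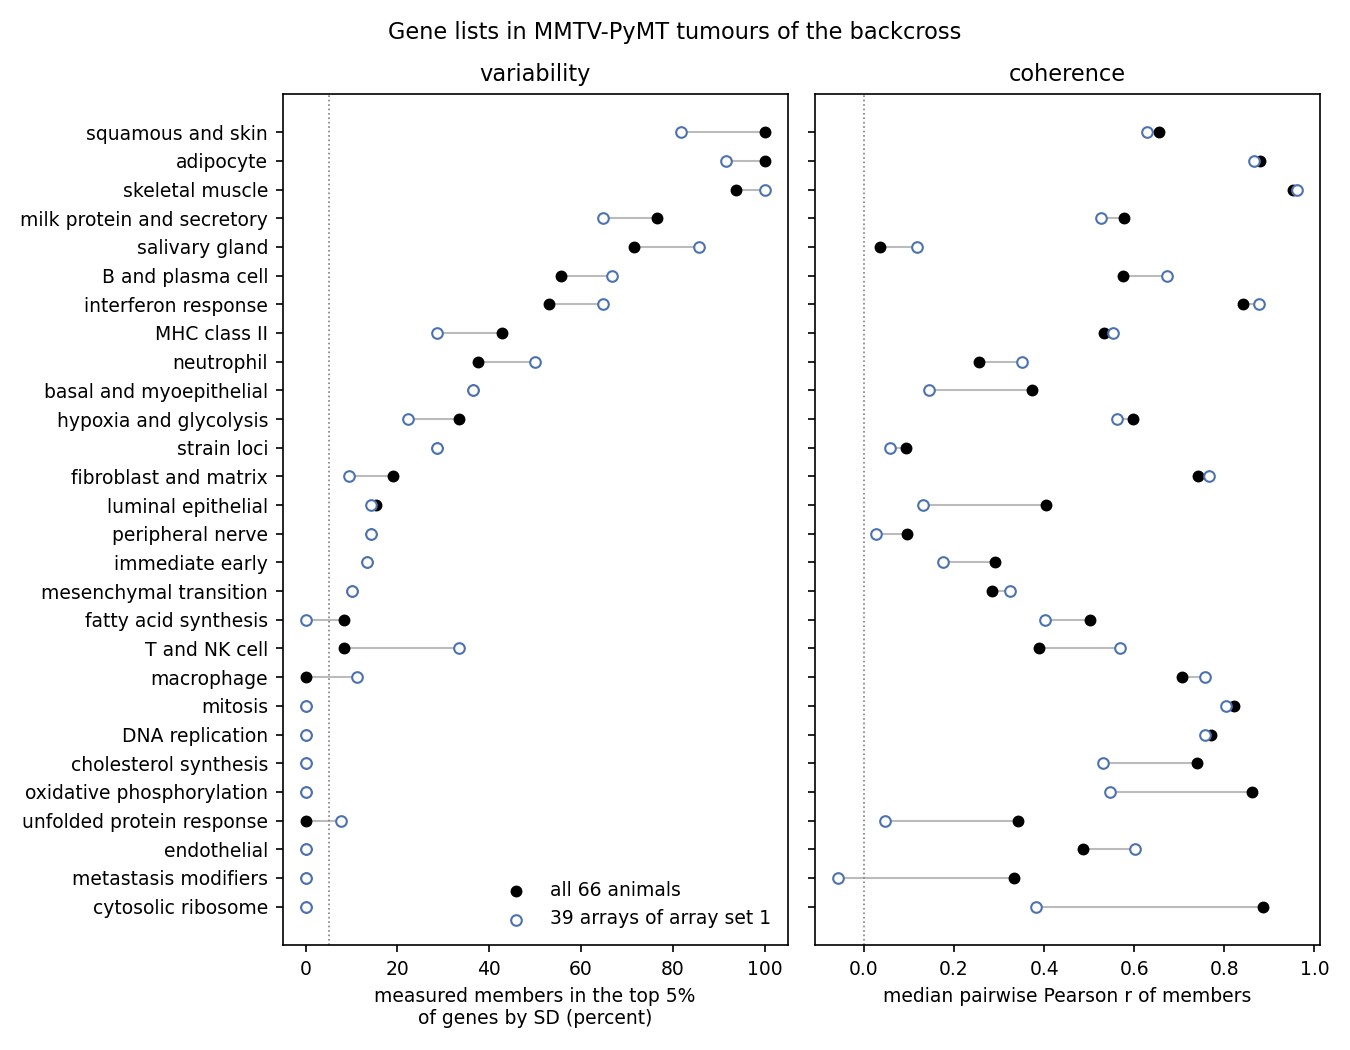
For each fixed list, the left panel gives the percent of measured members in the top 5% of genes by SD, with a dotted line at 5%, and the right panel the median pairwise Pearson r of members, with a dotted line at 0. Filled points are all 66 animals and open points the 39 arrays of array set 1, where skeletal muscle stays at 0.962 and metastasis modifiers are at -0.0573.

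Stromal cell types rose and fell together across tumours, and the T and NK cell score ran against mitosis. The macrophage and the fibroblast and matrix scores had a Pearson r of 0.854 and a Spearman rho of 0.883 over the 66 animals. Fibroblast and endothelial scores had r = 0.806 (rho 0.767), and adipocyte and skeletal muscle scores r = 0.624 (rho 0.651). T and NK cell scores rose with B and plasma cell scores (r = 0.641, rho 0.642) and were lower where the mitosis score was higher (r = -0.645, rho -0.655). Mitosis rose with DNA replication (r = 0.971, rho 0.946) and with hypoxia and glycolysis (r = 0.706, rho 0.739). All of these had permutation p = 1e-05 for both measures, the smallest that 100000 draws give, and adjusted p = 3.82e-05 for r over the 153 pairs tested. The draws did not keep the array sets, so these p also take in differences between array sets. So does the size of r for T and NK cells with mitosis. Every animal of array set 2 scored above 0 for T and NK cells and below 0 for mitosis, and within array set 1 that r was -0.421. Over all animals without the 2 farthest from the median, r was 0.833, 0.771, 0.580, 0.566, -0.637, 0.966 and 0.681 in the order given. T and NK cells with macrophages had r = 0.282 (p = 0.0215, adjusted p = 0.0425) and rho 0.267 (p = 0.0304, adjusted p = 0.0694), and r = 0.192 without 2 animals. Its size over all animals also depends on the array sets. Every animal of array set 2 scored above 0 for T and NK cells and below 0 for macrophages. Within array set 1 the pair had r = 0.621 (permutation, adjusted p = 0.000403) and 0.498 without 2 arrays. The pair T and NK cell with macrophage also turned to r = -0.0496 with a stricter filter on dim probe sets and -0.153 in the upper animal numbers, and did not pass in 4 of the other alternatives. Mitosis with fibroblasts (r = 0.247, p = 0.0465, adjusted p = 0.0868; rho 0.0498, p = 0.690; r = 0.0709 without 2 animals), mitosis with adipocytes (r = -0.036, p = 0.773; rho -0.0888, p = 0.479; r = -0.127 without 2) and T and NK cells with interferon response (r = 0.101, p = 0.420; rho 0.0889, p = 0.477; r = 0.121 without 2) did not pass.

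Within array sets, the stromal scores rose together in each set, and other relations moved. Macrophages with fibroblasts had r = 0.805 (rho 0.845) in array set 1 (permutation p = 1e-05 for both, n = 39), 0.677 (0.608) in array set 2 (permutation p = 0.0155 and 0.0397, n = 12), 0.880 (0.70) in array set 3 (exact p = 0.00284 and 0.0433, n = 9) and 0.972 (0.929) in array set 4 (exact p = 0.000149 and 0.00223, n = 8). Without 2 arrays r was 0.741, 0.433, 0.476 and 0.910. Fibroblasts with endothelium had r = 0.789, 0.875, 0.855 and 0.834 in the same order (rho 0.803, 0.818, 0.833 and 0.762; without 2 arrays 0.729, 0.899, 0.461 and 0.378). Mitosis with T and NK cells had r = -0.421 (rho -0.400) in array set 1 (permutation p = 0.00779 and 0.0123), -0.354 (-0.371) in array set 2 (permutation p = 0.271 and 0.235), -0.735 (-0.533) in array set 3 (exact p = 0.0290 and 0.148) and -0.970 (-0.929) in array set 4 (exact p = 0.000372 and 0.00223). Without 2 arrays r was 0.0325 in array set 3, so the relation there rests on those. T with B cells had r = 0.861, 0.919, 0.558 and 0.712 (rho 0.864, 0.552, 0.517 and 0.738), and in array set 2 it was 0.256 without 2 arrays. T and NK cells with macrophages had 0.621, 0.576, 0.706 and 0.938 (rho 0.536, 0.161, 0.467 and 0.905; -0.118 in array set 2 without 2 arrays), and mitosis with hypoxia 0.268, 0.601, 0.872 and 0.779 (rho 0.450, 0.483, 0.833 and 0.881). Mitosis with hypoxia did not pass in array set 1 by r (permutation p = 0.0973; 0.0040 for rho). Adipocytes with muscle had 0.586, 0.690, 0.511 and 0.741 (rho 0.655, 0.790, 0.567 and 0.786), and mitosis with DNA replication 0.955, 0.843, 0.939 and 0.975. Mitosis with fibroblasts, at 0.247 over all animals, had -0.237 (rho -0.276) in array set 1 (permutation p = 0.144 and 0.0908), 0.0438 (-0.00699) in array set 2 (permutation p = 0.892 and 0.991), -0.712 (-0.467) in array set 3 (exact p = 0.0311 and 0.213) and -0.882 (-0.81) in array set 4 (exact p = 0.00511 and 0.0218). Without 2 arrays r was -0.336, -0.144, -0.259 and -0.539. The p within array sets are not adjusted. Of the 153 pairs, 79 passed over all animals, 72 of them above 0, and 64 within array set 1, 50 of them above 0. Both shared 51 pairs with one sign and 2 with opposite signs.

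**Figure D3:**
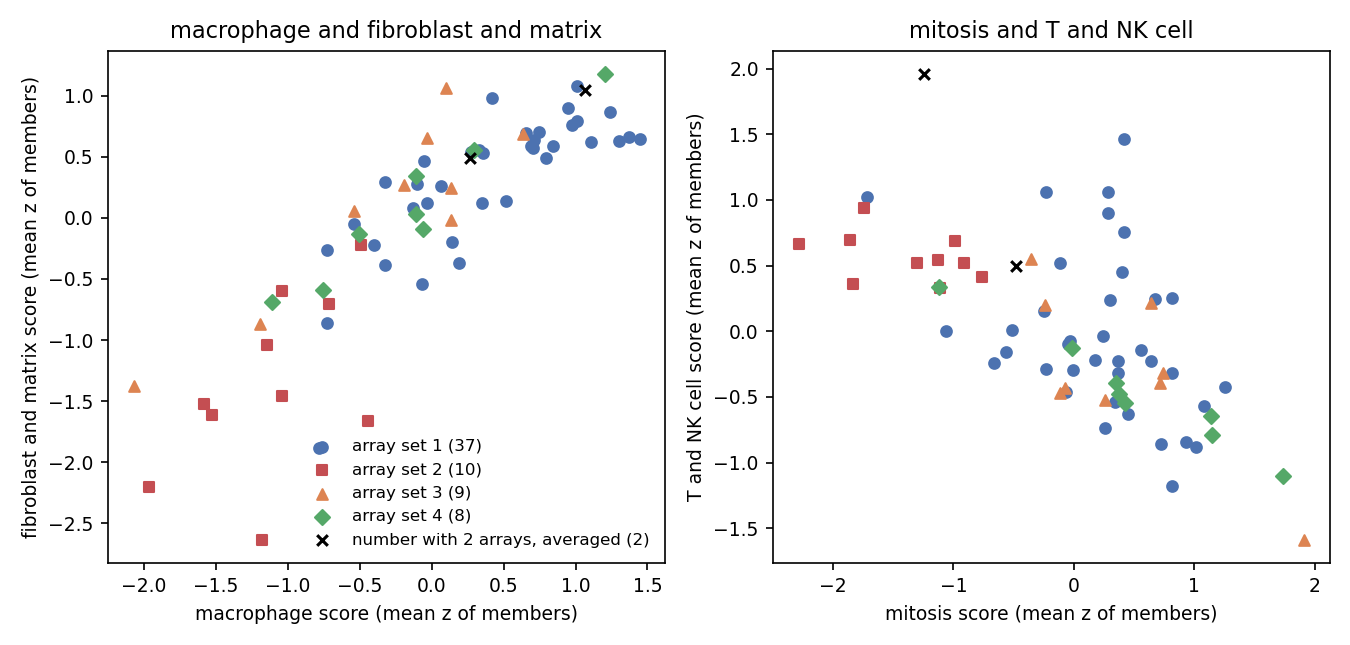
Each point is 1 animal, marked by array set, and both axes are list scores, the mean z-score of a list's measured genes over the 66 animals. The macrophage and fibroblast scores rise together (r = 0.854), and the T and NK cell score falls as the mitosis score rises (r = -0.645). The second r is in part a difference between array sets, as array set 2 lies apart in that panel. Within array set 1 it was -0.421.

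Many genes rose with the mitosis score, and the 10 that followed it most closely outside the lists included several of the cell cycle. The largest correlations were those of Dbf4, the activator of the kinase Cdc7 (r = 0.963), the condensin subunits Ncapg (0.955) and Ncaph (0.936), the cytokinesis gene Racgap1 (0.954), the kinetochore gene Ska1 (0.949), Topbp1, Melk, Cks2, Rad54l and Cenph, all 10 also called in array set 1 with r from 0.868 to 0.958. Their log2 values rose by 0.32 to 0.59 per SD of the score. Lower with the score in both were Phf1 (r = -0.783, and -0.640 in array set 1) and Tfeb, a regulator of lysosome genes (-0.756 and -0.578). Itgb5, Zdhhc14, Rab3a, Gpr162, Pik3r6 and Fam110c were lower over all animals and not called in array set 1, where their adjusted p ran from 0.0535 to 0.352, and other probe sets of Itgb5 and Zdhhc14 went the other way. Over all animals 20 of 21 DNA replication genes, all 15 of cholesterol synthesis, all 18 of oxidative phosphorylation, 16 of 18 hypoxia and 5 of 11 basal genes rose with the score, 1 DNA replication gene and 10 of 12 T and NK cell genes fell, and 0 of 7 MHC class II genes passed (the same counts over the list alone). Within array set 1, 20 of 21 DNA replication genes, 12 of 15 cholesterol synthesis genes, 6 of 18 oxidative phosphorylation genes and 2 of 18 hypoxia genes rose with the score (adjusted over the list alone, 21, 14, 9 and 2), while 6 of 11 basal, 4 of 7 MHC class II and 3 of 12 T and NK cell genes fell (6, 4 and 3 over the list alone). limma called 7338 genes higher and 1641 lower over all animals and 1418 and 746 in array set 1, with 1357 higher and 126 lower in both and 290 of opposite sign. The median correlation of all genes was 0.343 over all animals and -0.0208 in array set 1.

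Most B and plasma cell, macrophage and MHC class II genes rose with the T and NK cell score within array set 1. Outside the lists, Trav9d-3, a T cell receptor segment (r = 0.868), Rac2, a GTPase of blood cells (0.842), Gimap3 (0.841), the B cell attractant chemokine Cxcl13 (0.825), the homing receptor Ccr7 (0.815), Cd37, Myo1g, Rcsd1, P2ry13 and the lymphocyte integrin Itgb7 led, all 10 called in array set 1. The lower genes included Prelid2 (-0.733), Mastl, a mitotic kinase (-0.703), Atic, an enzyme of purine synthesis (-0.697), Pimreg, Gpsm2 and Spats2, and 9 of the 10 named by rule held in array set 1, all but Adgra3 (adjusted p = 0.0690). Of the fixed lists, all 9 B and plasma cell genes, 15 of 18 macrophage genes, 6 of 7 MHC class II genes, all 12 adipocyte genes and 9 of 16 endothelial genes rose with the score there (adjusted over the list alone, 9, 17, 6, 12 and 13), and 11 of 27 mitosis genes fell (19). Over all animals the counts were 8 of 9, 7 of 18, 3 of 7, 10 of 11 and 10 of 16 higher in the same order, and 26 of 27 mitosis genes and 1 endothelial gene lower (27 mitosis genes over the list alone, the others as given). limma called 1747 genes higher and 6272 lower over all animals and 941 and 496 in array set 1, with 579 higher and 470 lower in both and 18 of opposite sign.

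Macrophage, endothelial and adipocyte genes rose with the fibroblast and matrix score, among many others. Outside the lists, Pcolce, an enhancer of procollagen cleavage (r = 0.940), Loxl1, which cross-links elastin (0.922), Medag, Bicc1, Lsp1, Cpxm1, Spon1, the complement inhibitor Serping1 (0.890), Srpx2 and Cd34, a marker of endothelial and stromal progenitors (0.883), were all called in array set 1, with r from 0.843 to 0.938. Lower genes included the neutrophil chemokine Cxcl1 (-0.675, and -0.478 in array set 1), Ppp2r1a (-0.691 and -0.482) and Grik3 (-0.672 and -0.560), and of the 10 named by rule 5 were tested and 3 held in array set 1. Other probe sets of Ppp2r1a and Grik3 went the other way. Of the lists, 17 of 18 macrophage genes, 14 of 16 endothelial genes, all 12 adipocyte genes and 7 of 10 genes of mesenchymal transition rose with the score in array set 1 (adjusted over the list alone, 17, 14, 12 and 7), and 4 of 18 hypoxia genes fell (6). Over all animals the counts were 18 of 18, 15 of 16, 11 of 11 and 7 of 10 higher, and of the hypoxia genes 4 were higher and 4 lower (2 and 4 over the list alone, the others as given). limma called 7398 genes higher and 1410 lower over all animals and 1078 and 330 in array set 1, with 975 higher and 64 lower in both and 101 of opposite sign.

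Skeletal muscle, endothelial and fibroblast genes rose with the milk protein score, among many others. The leading genes outside the lists were Chrdl2 (r = 0.843), Igfals, a subunit of the circulating insulin-like growth factor complex (0.836), the folate receptor Folr1 (0.820), Pla2g15, Duox1 and its maturation factor Duoxa1, Clu, the lipase cofactor Abhd5 (0.796), Slc28a3 and BC016548, all 10 called in array set 1. Spata5, Zbtb10, Rttn, Ptprg, Chrm1, Fcsk, Ndrg4, Dhtkd1, Polr3k and Trub2 were lower, with r from -0.70 to -0.649, and all 10 held in array set 1, with adjusted p up to 0.0494, though other probe sets of Spata5, Ndrg4 and Polr3k went the other way. Among the lists, 11 of 16 skeletal muscle genes, 12 of 16 endothelial genes, 11 of 21 fibroblast genes, 8 of 18 macrophage genes and 5 of 12 fatty acid synthesis genes rose with the score in array set 1 (adjusted over the list alone, 16, 14, 18, 15 and 7). Over all animals the counts were 16 of 16, 13 of 16, 21 of 21, 17 of 18 and 10 of 12 (18 macrophage genes over the list alone, the others as given). Cytosolic ribosome genes turned, with 10 of 11 higher over all animals, and 0 higher and 3 lower in array set 1 (7 lower over the list alone). The milk list itself did not pass the coherence test over all animals. limma called 6798 genes higher and 1437 lower over all animals and 913 and 1048 in array set 1, with 798 higher and 191 lower in both and 274 of opposite sign.

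For 9 genes the 66 animals fell into 2 separate levels. BC018473, on chromosome 11, stood at 11.65 ± 0.84 in 36 animals and 3.79 ± 0.69 in 30 (log2, SD), and D17H6S56E-5, on chromosome 17, at 10.95 ± 0.34 in 30 and 7.73 ± 0.31 in 36. H2-Eb1, a class II antigen-presenting chain on chromosome 17, stood at 8.86 ± 0.49 in 28 and 6.41 ± 0.36 in 38. Rbm45 (chromosome 2), Mir1931 (10), D730005E14Rik (15) and Zfp979 (4) were also called. The sizes of the 2 sides were not apart from 1:1 for these 7 genes, with exact binomial p from 0.109 to 0.902. Ms4a1, which encodes the B cell marker CD20 on chromosome 19, was higher in 14 and lower in 52 (exact binomial p = 2.82e-06), where 14 is the smallest side that the 20% rule allows. Its sides in array set 1 were 13 and 26 (exact binomial p = 0.0533). Rab1b, on the same chromosome, was higher in 42 and lower in 24 (p = 0.0356). The Rab1b split largely followed the array sets. All animals of array set 2 (8.07 to 8.38) and array set 3 (8.31 to 8.55) lay at its lower level. All of array set 4 (9.42 to 9.69) lay at the upper, as did array set 1 apart from animals 2421, 3290 and 3853. A single backcross locus would put animals on both sides at about 1:1 within array set 1 too. These values therefore argue against genotype as the source of the Rab1b split. The lower levels of BC018473, Ms4a1 (3.81), Mir1931 (3.09), D730005E14Rik (4.11) and Zfp979 (4.15) lie below the median of all values (5.42) and are not shown to be above background, so their distances are not exact. For Mir1931 the upper level (5.34) lies below that median too. D ran from 10.25 for BC018473 to 5.25 for Zfp979, with adjusted p from 0.00322 to 0.0473. D within array set 1 was larger for 8 of the 9, as for BC018473 (20.78) and D17H6S56E-5 (12.78), and 1.73 for Rab1b, where animals 2421 (8.41), 3290 (8.38) and 3853 (8.37) lay at the lower level, fewer than the 8 arrays that the smaller side must hold. With the same uniform null 4 of the 9 were called there, and 5 genes in all, the other being Tnfsf13os (chromosome 11, D 7.37).

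**Figure D4:**
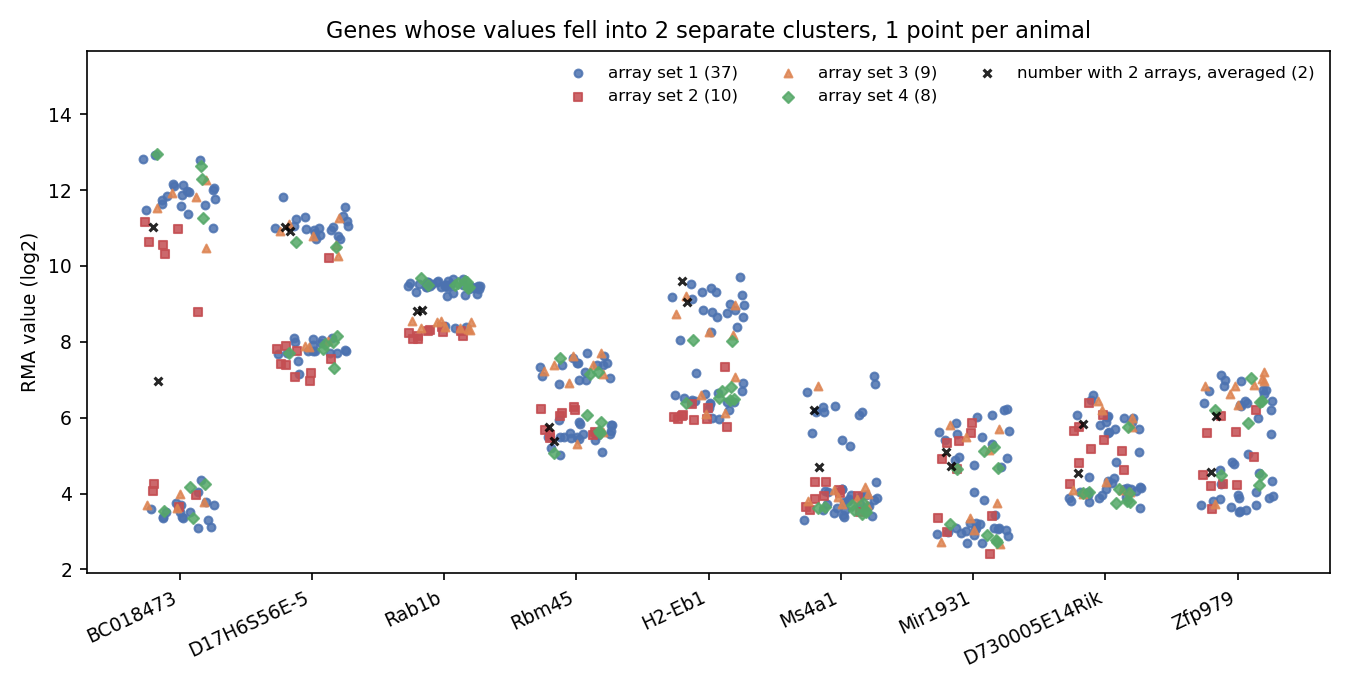
Each point is 1 animal's log2 value for 1 of the 9 two-cluster genes, spread sideways at random and marked by array set. Crosses are the 2 numbers with 2 arrays, averaged, which is why 1 of them stands between the levels of BC018473.

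Neighbouring two-cluster genes split the animals alike in part. Over all animals the 2 pairs within 10 Mb, H2-Eb1 with D17H6S56E-5 and Ms4a1 with Rab1b, had a median agreement of 75.8%, against 54.6% for permuted positions (one-sided permutation p = 0.0276). The first pair agreed in 96.97% of animals and the second in 54.55%, so the result rests on 1 pair. In array set 1 with the uniform null 1 such pair remained (100%, p = 0.101). A setting added after the data were seen, array set 1 with the null of normal samples, called 42 genes on 15 chromosomes, 28 of them with sides not apart from 1:1. Of the 18 neighbouring pairs, 12 agreed in at least 85% of arrays, and the median was 94.87% against 56.41% for permuted positions (p = 0.0001, the smallest the 10000 permutations can give). Most of the 18 pairs lie among Akap8l, D17H6S56E-5, H2-Ea, H2-Eb1 and H2-Ob, all on chromosome 17, so the pairs are not independent. Named after their values were seen, BC018473 and St6galnac1 on chromosome 11 agreed in all 39 arrays, as did Metap1d and Rbm45 on chromosome 2 and H2-Eb1 and D17H6S56E-5 on chromosome 17. Apobec3, a cytidine deaminase that restricts retroviruses, and D730005E14Rik on chromosome 15 agreed in 38 of 39, and so did Aqr and Ndufaf1 on chromosome 2. Akap8l on chromosome 17 split the arrays on the opposite sides of H2-Eb1 in 38 of 39. Pairs 10 to 50 Mb apart agreed in a median of 61.54% (p = 0.0044). Atp2a1 and Mylpf, neighbours on chromosome 7, are both in the skeletal muscle list, which held 5 of the 42 genes. On the X chromosome 0 of 391 genes were called over all animals, against 9 of 12457 on autosomes, and 0 of 376 against 5 of 12085 in array set 1 (Fisher's exact test, two-sided, p = 1 for both).

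Of the loci known to differ between mouse strains, 7 genes were measured and 0 passed the two-cluster test over all animals. H2-Ea, a class II chain that some mouse haplotypes lack, had levels of 9.36 ± 0.40 in 31 animals and 7.80 ± 0.41 in 35 (D 3.86), and Ifi202b, an interferon-inducible gene, 9.59 ± 0.58 in 44 and 7.50 ± 0.62 in 22 (D 3.47). Both were called in array set 1 with the null of normal samples (adjusted p = 0.0454 and 0.0360). The probe set standing for H2-Ea had D 4.52 there. A further bright probe set of H2-Ea had D 7.70, with means of 9.89 in 21 arrays and 5.93 in 18. It put 94.87% of arrays on the same side as the first. H2-K1, H2-D1, Ifi203, Ifi204 and Fcgr2b had D from 2.13 to 2.85 over all animals and were called in neither setting. The probe sets of H2-D1 disagreed: the one standing for the gene had D 2.65 in array set 1, and 3 others had D 19.38, 13.48 and 13.96, each with 21 arrays above and 18 below. Among metastasis modifiers, Cnot2 (SD 0.52), Sipa1 (0.43), Brms1 (0.42) and Cd82 (0.39) varied most over all animals. Within array set 1 their SDs were 0.15, 0.17, 0.16 and 0.28. Mtdh, Cadm1, Rrp1b, Arid4b, Csf1 and Nme1 had SDs from 0.15 to 0.32 over all animals, and none of the 10 was a two-cluster gene.

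Arrays with R in the title differed from the others in many genes, along the lines of the array sets. Higher in the 10 R arrays than in the 58 others were Pabpc4l (by 1.16 ± 0.22, log2 and SE), the monoamine transporter Slc18a2 (1.13 ± 0.17), Map3k12, Sephs2, an enzyme of selenoprotein synthesis (1.07 ± 0.15), Phxr4, Igsf3, Gsdme, Rpl27a, Rbms3 and Cnnm4. Lower were the nuclear RNA Malat1 (-2.27 ± 0.43), Evi5 (-1.75 ± 0.31), the splicing factor Srrm2 (-1.67 ± 0.34), Otub1, Pfn1, which binds actin monomers (-1.33 ± 0.17), Sp3, Gatad2b, Decr2, Fbrsl1 and Npepps. limma's adjusted p for these genes was at most 0.0260. Of the lists, 4 of 13 luminal genes, 3 of 15 immediate early genes, 2 of 18 macrophage genes, 2 of 18 oxidative phosphorylation genes and 2 of 16 endothelial genes were lower (adjusted over the list alone, 4, 3, 6, 3 and 2), while 1 endothelial gene was higher, and 1 immediate early gene was higher over the list alone. In each other list at most 1 gene passed. limma called 463 genes higher and 698 lower. All 10 R arrays are in array set 2 or 3, and with array set as a covariate it called 0 higher and 1 lower, with 727 at an unadjusted p under 0.05. In that fit Pabpc4l (-0.36), Slc18a2 (-0.20), Map3k12 (-0.19), Rpl27a, Gsdme, Cnnm4, Malat1 (0.34), Fbrsl1 and Npepps had the opposite sign, and the adjusted p of all the genes named was at least 0.863, so suffix and array set cannot be told apart here for most of these genes.

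Animals of the upper number range differed from those of the lower in genes that also follow the array sets. Higher in the 18 upper animals than in the 48 lower were Polr2a, the large subunit of RNA polymerase II (by 0.74 ± 0.12, log2 and SE), the Wnt co-receptor Lrp5 (0.73 ± 0.16), Epop, Anpep, Zfp395, Atn1, Scaf1, the apoptosis effector Bak1 (0.66 ± 0.13), Espn and Pcgf2. Lower were Cyp24a1, which breaks down vitamin D (-0.64 ± 0.18), Mapre2, the lipolysis inhibitor G0s2 (-0.59 ± 0.18), Ceacam20, C130075A20Rik, Tnfaip2, Bace1, the transcription factor Maf (-0.53 ± 0.14), Lncppara and the mucin Muc15. limma's adjusted p for these genes was at most 0.0478. In each fixed list at most 1 gene passed, as 1 of 16 endothelial genes, lower, and 1 of 27 mitosis genes, higher (adjusted over the list alone, 2 and 1). The median difference of skeletal muscle genes was -0.99 with 0 of 16 passing, over the list alone too. Another probe set of Mapre2 went the other way, and Lrp5 turned to -0.0376 after centring within array sets. limma called 347 genes higher and 112 lower over all animals, and 2084 higher and 646 lower without array set 2. Within array set 1, with 4 upper animals, it called 0, with 1329 at an unadjusted p under 0.05, and after centring within array sets 0, with 141. All 8 arrays of array set 4 are of the upper range.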

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

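The array set settings were chosen after the data were seen, and the others before the data were examined. The number of lists called for variability and coherence moved beyond 1.5 times in 0 of 14 and 0 of 13 alternatives. Of the SDs of the 30 most variable genes, 354 of 355 alternatives stayed within their spread. The cause of the changes given here was not tested.

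The number of two-cluster genes was 1235 with a smaller side of at least 10%, 1175 with the null of normal samples, 51 with 68 arrays as separate samples, 17 with the probe set of largest SD and 5 with the stricter filter. It was 18 without array set 2, 5 in array set 1, 42 there with the null of normal samples, and 3 centred within array sets. The linkage of two-cluster genes, as median agreement, was 96.97% with a smaller side of at least 10%, below the 98.48% of permuted positions (p = 1), and 90.91% with the null of normal samples (p = 1). It was 94.12% with 68 arrays (p = 0.211), 75.78% without the numbers that have 2 arrays (p = 0.0869), 96.97% with the stricter filter (p = 0.101) and also with the 3' to 5' residuals (p = 0.0683), 73.96% in the lower numbers (p = 0.152) and 100% in array set 1 (p = 0.101). Its p ran from 0.0001 to 1 over 16 alternatives. The odds ratio of X-linked two-cluster genes was 0.644 with the null of normal samples (p = 0.0396).

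Of the list pairs, 33 passed in the upper numbers. The pair mitosis with fibroblast and matrix had r = -0.443 without array set 2, -0.234 in array set 1 and -0.336 after centring. The pair mitosis with adipocyte had 0.00722 in the lower numbers, and T and NK cell with macrophage -0.0496 with the stricter filter and -0.153 in the upper numbers. The median r behind list coherence: salivary gland was -0.059 in the upper numbers, that of list coherence: peripheral nerve -0.0184 with the probe set of largest SD and -0.0274 in the upper numbers, and that of list coherence: metastasis modifiers -0.0124 without array set 2, -0.0573 in array set 1 and -0.0224 after centring. Centred ranks for the same animal number were 1 for 3296 and 206 for 3351.

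Without array set 2, in array set 1 and after centring, the genes with the mitosis score numbered 3262, 2164 and 4269, genes with the T and NK cell score 2845, 1437 and 3709, genes with the fibroblast and matrix score 2377, 1408 and 2522, and genes with the milk protein and secretory score 3177, 1961 and 2808. By Spearman correlation 5672 went with the fibroblast and matrix score. The animal number range gave 2730, 0 and 0 in those settings. The suffix R gave 1 with array set as covariate, 2066 with the probe set of largest SD and 107 with the 3' to 5' residuals.

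Some named genes changed sign with another probe set, per SD of the score. With the largest SD these were Itgb5 (0.13) and Zdhhc14 (0.42) for mitosis, Grik3 (0.0822) for fibroblasts, Spata5 (0.29) and Polr3k (0.23) for milk, and Mapre2 (0.25) for the number range. Without _x_at and _s_at probe sets they were Itgb5 (0.0277), Ppp2r1a (0.13) for fibroblasts, and Ndrg4 (0.0264) and Polr3k (0.24) for milk. Cbs turned to 0.0104 with no filter, and Lrp5 to -0.0376 after centring. With array set as a covariate for the suffix R, Pabpc4l turned to -0.36, Rpl27a -0.19, Slc18a2 -0.20, Map3k12 -0.19, Gsdme -0.22, Cnnm4 -0.30, Malat1 0.34, Fbrsl1 0.0563 and Npepps 0.0635. The two-cluster results of single genes had 221 of 250 alternatives on the same side of the threshold, with 24 lost and 5 gained.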

Other observations

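Tests of the array set 2 pattern and of neighbouring genes, and that of an inherited locus for B cell markers, were chosen after the results were seen, while those of the X chromosome, of random splits and of lymph node genes were planned first. Some biology lies outside the comparisons above. In array set 1, genes that split the arrays as Ms4a1 does in at least 90% of the 39 were Cd3d, a chain of the T cell receptor complex, Cd79a, a chain of the B cell receptor, Gimap3, H2-Ob, the immunoglobulin segment Ighv14-2 and the macrophage receptor Marco, chosen after their values were seen. Ighv14-2 and Ms4a1 lay on the same side in 97.44% of arrays, with means of 6.96 in 12 arrays and 3.87 in 27. Marco stood at 7.21 in 10 arrays and 4.48 in 29. Other pairs of scores also passed in array set 1: adipocytes with endothelium had r = 0.752 (rho 0.762, 0.666 without 2 arrays), MHC class II with macrophages 0.875 (0.869, 0.836) and mitosis with cholesterol synthesis 0.758 (0.775, 0.718), each with permutation p = 1e-05, the smallest possible, and adjusted p = 0.000102 over 153 pairs.

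B cell markers such as Ms4a1 jumped together in some tumours. Ms4a1 and the genes that split like it lie on 7 chromosomes, which leaves an inherited locus open, since one that acts on lymphocyte content would move genes on any chromosome. A candidate explanation is lymph node tissue in some of the tumour pieces. Of 15 lymph node genes listed before the test, 7 were measured and not in the B and plasma cell list, and none of these was in another list. Their median Spearman correlation with the B and plasma cell score in array set 1 was 0.748, from Cxcl13 (0.810; mean 5.80, highest 6.99), Ccr7 (0.804), Cd37 (0.749), Ltb (0.748; highest 8.30), Coro1a (0.671; highest 9.79) and Tnfrsf13c (0.532) to Siglec1 (0.121), and lymphocytes that gathered within the tumour, which carry most of the same genes, were not tested apart from it.

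The 12 arrays of array set 2 stood apart in 2434 probe sets. The lowest 18S mean among them lay 2.13 log2 units above the highest of the other arrays, so labelling that took in ribosomal RNA may account for the pattern. A difference between the animals is argued against by the numbers with arrays inside and outside the set, whose 18S means differed by 3.55 and 2.98 log2 units, as far as a number names 1 animal, which is open for 3351. Poorer RNA stays open: the Gapdh 3' minus 5' difference was higher by 0.106 SD of the other arrays, and that of Actb by 1.652 SD. No other biological explanation was tested, since the labels give 1 group.

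Neighbouring two-cluster genes split the arrays of array set 1 alike (median 94.87%), in a setting that was 1 of 16 alternatives and was chosen after the data were seen. Differences between the array sets are excluded as the cause, since this value was measured within 1 of them. Smaller technical groups within array set 1 are not excluded, since the search took no split with under 15% of arrays on the smaller side. The median lay above the upper limit of permuted positions (60.26%). Without genes of the program lists the median over 8 pairs on 5 chromosomes was 97.44% (upper limit 61.54%). That argues against shared cell content only as far as those lists capture it. The genes left still held H2-Ea, a class II chain, and Gimap3 and Marco, which split as Ms4a1 does, so cell content is not excluded. Inherited loci are a candidate explanation (permutation p = 0.0001, the smallest possible), and over all animals with the null of normal samples the agreement did not exceed that of permuted positions. Whether the transcript level or only the binding of a probe to a strain variant differs stays open: of 21 genes with a neighbour, 6 had a further bright probe set and 4 of these had one that agreed in at least 90% of arrays, and the probe sets of H2-D1 disagreed.

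Of 100 splits of the arrays into the same sizes, 1, the real one, gave as many genes as the suffix R (1161, the highest other 6). For the animal number range 2 of 100 did, the real one with 459 and one with 3929, which had 6 animals of array set 2 in its smaller group and points to that structure of the samples; the next highest was 231, and after centring within array sets limma called 0 genes for the real one (141 at an unadjusted p under 0.05). These splits did not keep the array sets, with which both groupings overlap, so what they exclude is chance without that structure, and for the number range chance within array sets stays open. X-linked genes had an odds ratio of 0 among two-cluster genes (0 of 391, p = 1), which with 9 genes called does not decide whether the parent with NZB genes was male.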
